A study of Homo sapiens with 6 samples.

How the data were processed

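The data were 6 libraries of LS 174T cells, 3 untreated and 3 given 4 mM propionate for 4 h. Per the labels' protocols, libraries were made from 500 ng of total RNA with a Lexogen QuantSeq kit, which counts reads near the 3' end of polyadenylated transcripts. The catalogue number beside that name may belong to another kit of the maker, and no read position is in the tables to settle it. Groups were taken from the sample titles, and replicate numbers from the marks that tell apart the titles of a group. The submitters' processing notes name Bowtie2, edgeR and the genome builds hg19 and GRCh37, with no version and no role. The read counter, its strand setting and the gene annotation are not given in the sources used here. Unstranded counting would mix the reads of genes that overlap on opposite strands.

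The authors deposited raw read counts per gene symbol, one table per library, and the values are whole numbers whose totals differ between libraries. Each table had 25737 lines with 24462 different symbols. For the 286 symbols on several lines the counts were summed, and for 30 of these more than 1 line held reads. No line lacked a gene name, and 5039 symbols had no read in any library. The 8 symbols with at least 100 reads whose 6 counts equal those of another symbol are likely the same reads counted under both names and were kept. Totals per library were 11603288, 11824915 and 11921005 reads in control and 12746170, 12597381 and 11645597 with propionate, which set the limit of 3 reads at 0.235 to 0.259 CPM. The deposited tables record no molecular identifiers, so reads are not known to be independent molecules. Libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom between 6.01 and 8.85 over genes with at least 20 reads. Preparations of 1 RNA can also differ this much, so this does not show that they are biological replicates. The libraries were taken as replicates from the labels' design.

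Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on the 13605 genes kept by filterByExpr, with TMM factors, no covariate, both directions, and a Benjamini-Hochberg adjusted p under 0.05. CPM values (reads scaled to a library total of 1000000) used the TMM factors, and fold changes came from the fit with its prior count of 0.125. For genes with 10 or fewer reads in a group, the ratio of summed reads over summed library totals is given with an exact binomial 95% interval. Gene lists (44, with 43 having at least 5 tested members) were written down beforehand and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 43 lists. With an estimated correlation camera uses the residual degrees of freedom of the fit, which are few with 6 libraries. Its p is then larger even where the estimated correlation is low, as for immediate early genes (-0.00205) and ERK genes (-0.0122). Some lists share members: without those shared with another called list, the lists of hypoxia-inducible factor targets and of glycolysis missed the threshold (adjusted p = 0.0678 and 0.0781) and the other 8 passed.

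The genes named in the text were set by a rule: MUC2, MUC5AC, EPAS1, HIF1A, SLC16A1, CDKN1A and H1F0 always, the 12 largest rises and 12 largest falls among called genes above 5 CPM in the higher group whose libraries do not overlap, and up to 4 members of each list with the smallest p per direction. Some results that this rule selects were left out of the text. The groups, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except those said to be added. Families of genes with a shared symbol prefix, lists without shared members and the GC versions were added afterwards.

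Each group has the replicate numbers 1 to 3. Deviations of libraries with the same number from their group means correlated at 0.238, 0.393 and 0.44 over genes above 10 CPM, all above the limit of 0.1 set for pairing, so the numbers were taken to pair the samples. Libraries of unlike number correlated between -0.352 and 0.0104. Deviations from a mean of 3 libraries cancel out within a group, so some matching of the libraries would correlate positively without any pairing. These values are thus weak evidence for the pairing, which comes from the data, as no label states a shared day or batch. The fit with the replicate number as a block was run as an alternative, and its p-values depend on this pairing.

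Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters on low counts, other thresholds, the replicate block, thinning to 11603288 reads and leaving out each library. A correction for transcript GC content was added after the data were seen. It used splines with 4 degrees of freedom on the GC content of each gene's transcript and of its last 500 bases in GENCODE release 29, which matched 22622 symbols. Each library's fitted trend was subtracted in the fit with the replicate block. It was first run as fitted. After its result was seen, versions with 1 of the GC measures and versions recentred to a median of 0 in each library were added, and all 6 are reported. The reference is of build GRCh38, so it served only for sequence composition and for which genes overlap, and no coordinates are given.

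The test was checked on simulated counts for the comparison of propionate with control, with 13459 genes tested. It recovered 10% of genes changed 1.25-fold, 68% of those changed 1.5-fold, 87.8% at 2-fold and 97.9% at 4-fold, and 6% of its calls were false. The simulation had no replicate block and no GC trend, and it changed a far smaller share of genes than the 34.2% called in the data. These shares therefore hold for the fit without the block in that setting and need not carry over to the real data. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).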

Results

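Gene expression was measured by RNA sequencing, of 3' ends if the kit name in the labels is right, in LS 174T, a human colorectal adenocarcinoma line that makes gel-forming mucins and is used as a goblet cell model. Cells were left untreated (control, n = 3 libraries) or given 4 mM propionate, a short-chain fatty acid that gut bacteria produce from fiber, for 4 h (n = 3 libraries). The total per library ranged from 11603288 to 12746170 reads over 24462 gene symbols, and 13605 genes had enough reads to be tested. At these depths a count of 3 reads corresponded to between 0.235 and 0.259 CPM (reads scaled to a library total of 1000000). The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Intervals made from read counts cover counting error only.

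Propionate was followed by a broad change in transcript levels. Among the tested genes, 2343 were higher and 2316 were lower with propionate, which together made 34.2% of the genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The largest changes were rises: 155 of the called genes were at least 4-fold higher and 10 were at least 4-fold lower. In control, 214 of the higher genes averaged under 1 CPM, so their folds rest on few reads. With a 2-fold change required as well, 681 genes were higher and 270 were lower. In 45.2% of the tested genes the 3 propionate libraries lay all above or all below the 3 controls, where chance gives 10%. The first principal component of log2 CPM held 72.8% of the variance and separated the groups. The called genes followed transcript GC content: in the fifth of genes with the highest GC content 868 were higher and 233 lower, and in the fifth with the lowest 217 were higher and 587 lower.

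Among called genes above 5 CPM in the higher group whose libraries did not overlap, the largest rise was that of ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase. Its 6 reads over the 3 controls became 246 reads with propionate, a ratio of 39.2 after scaling to library totals (95% interval 17.7 to 108), with an adjusted p of 1.23e-07 by edgeR. APLP1, a relative of the amyloid precursor protein, went from 10 to 227 reads (ratio 21.7, 11.6 to 45.9). Control library 1 held most of the control reads of both genes, and without it the fitted log2 fold change was 6.13 against 5.19 for ANGPTL4 and 5.48 against 4.38 for APLP1. LYPD3 rose 13.6-fold, from 1.41 ± 0.636 to 19.5 ± 2.72 CPM (mean ± SD, n = 3), and GIPR, the receptor for the incretin hormone GIP, rose 9.86-fold. LGALS1, which encodes galectin-1, rose 7.20-fold, from 6.30 ± 0.503 to 45.4 ± 4.58 CPM. HES2, the pro-apoptotic gene BMF, the prostaglandin E synthase PTGES, LMTK3, the GTPase gene RHOV, LINC00341 and SCAMP5 rose between 6.63-fold and 8.49-fold. The largest falls were smaller. EPC2, a subunit gene of the NuA4 acetyltransferase complex, fell 4.88-fold, from 23.4 ± 2.29 to 4.80 ± 0.993 CPM. ASCL2, a transcription factor of intestinal stem cells and the most abundant gene among the large falls, was 3.70-fold lower, going from 574.7 ± 30.6 to 155.5 ± 13.9 CPM. OR51E1, an olfactory receptor gene whose product responds to short-chain fatty acids, was 3.76-fold lower. PRDM15, ZNF784, ATXN7L2, the prostaglandin D2 receptor gene PTGDR, RGMB-AS1, PTPRO, FAM217B, ZNF532 and C9orf156 fell between 3.23-fold and 3.95-fold. RGMB-AS1 and FAM217B overlap RGMB and PPP1R3D on the opposite strand, and since the strand setting of the counting is not given, reads of the overlapping genes cannot be assigned with certainty.

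**Figure D1:**
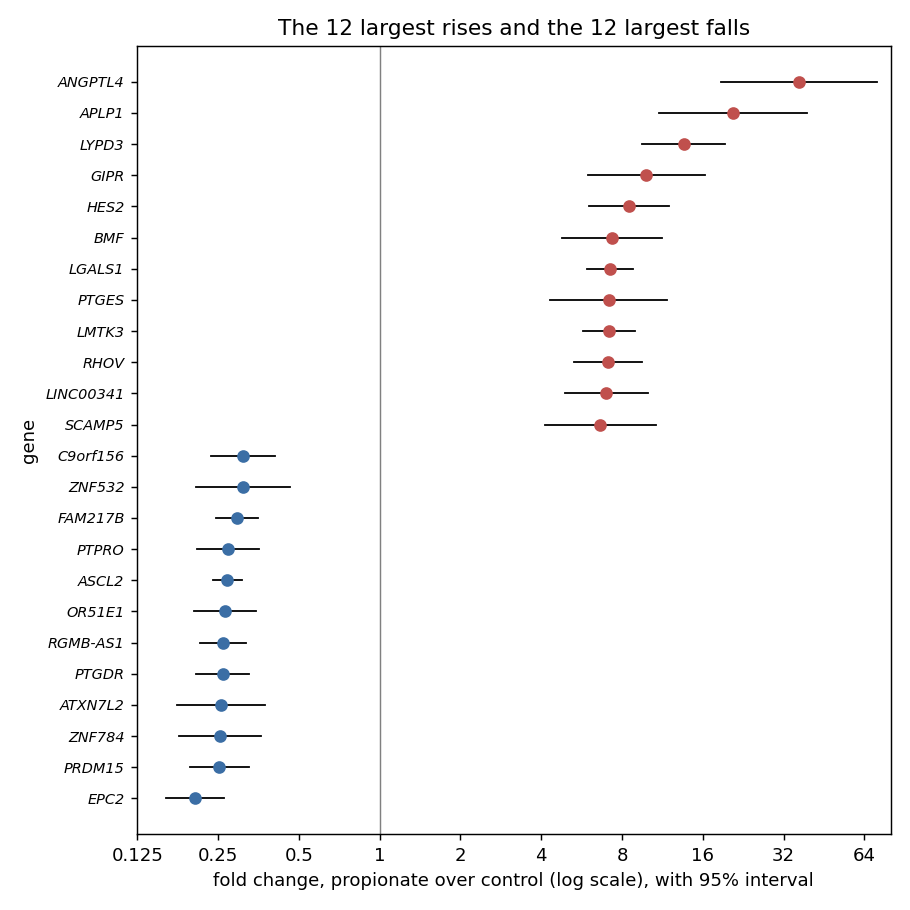
Fold change of the 12 genes with the largest rise (red) and the 12 with the largest fall (blue), propionate over control on a log axis, each with its 95% interval from the fit (n = 3 libraries per group). The rises reach 36.6-fold in the fit for ANGPTL4, while the largest fall, that of EPC2, was 4.88-fold.

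The series title asks whether propionate raises MUC2, the gel-forming mucin of intestinal goblet cells. MUC2 was 1.19-fold higher with propionate, at 202.7 ± 20.5 CPM in control and 240.8 ± 20 CPM with propionate (log2 fold change 0.25, SE 0.0905, edgeR adjusted p = 0.0396). The libraries of the groups overlapped, and MUC2 was higher with propionate in all 3 same-number pairs. This call did not hold when propionate library 1, propionate library 2, control library 1 or control library 3 was left out (adjusted p between 0.0817 and 0.184), and with the GC trend of each library removed in a fit with the replicate block the log2 fold change was 0.04 (SE 0.0525, adjusted p = 0.615). Over its 23 alternatives the adjusted p of MUC2 ran from 0.000264 with the block to 0.955, and the GC value of MUC2 comes from a reference transcript of 393 bases, which may not represent the whole gene. MUC5AC, the gastric-type gel-forming mucin that this line also expresses, was at 235.2 ± 27.2 and 234.7 ± 30.7 CPM (log2 fold change -0.00, SE 0.0994, adjusted p = 0.988), and with the GC trend removed in the blocked fit it was lower (log2 fold change -0.24, adjusted p = 0.000384, with a range of 1.81e-05 to 0.994 over its alternatives).

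Of 36 measured genes of secreted mucins, goblet cell products and secretory lineage regulators, 8 were higher and 5 were lower, and the same counts were found adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.645), and its median was above 0 with each scaling but below 0 with the GC trend removed and without control library 1. The rises were led by RAP1GAP (2.19-fold), by SYTL2, a gene of vesicle exocytosis (3.69-fold, from 2.79 ± 0.319 to 10.3 ± 0.460 CPM), by KLF4, a transcription factor of goblet cell differentiation (2.53-fold) and by FOXA3 (1.67-fold). The falls were led by ERN2, the stress sensor of mucus-producing cells (1.88-fold lower, from 257.7 ± 33.2 to 137.1 ± 17.1 CPM), by FOXA1 (2.55-fold lower), by the sialyltransferase ST6GALNAC1 (1.72-fold lower) and by RETNLB (1.95-fold lower). ERN2 overlaps PLK1, which also fell, on the opposite strand. Among 29 glycosyltransferases that build mucin O-glycans, 9 were higher and 4 lower (10 and 4 adjusted over the list alone, camera adjusted p = 0.265), with ST3GAL2 higher and FUT2 lower. Of 7 measured cell surface mucins only MUC1 passed, rising from 0.710 ± 0.398 to 2.74 ± 0.489 CPM.

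**Figure D2:**
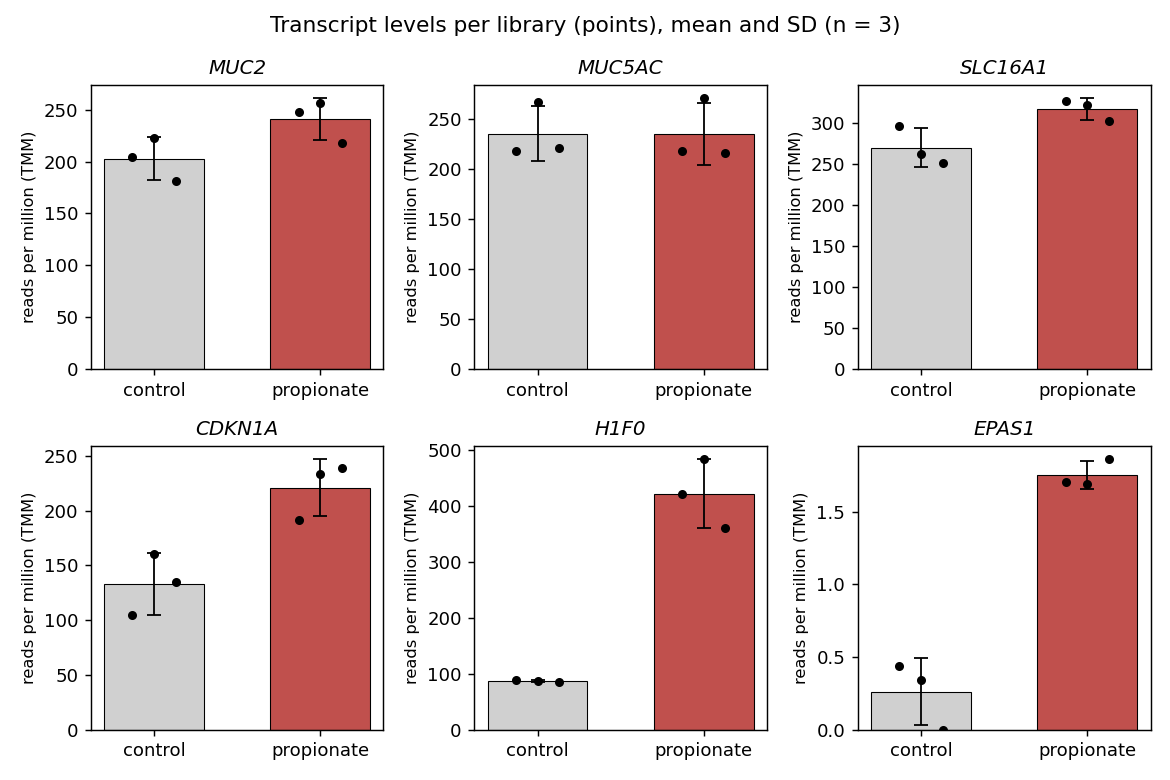
Transcript level in TMM-scaled CPM for MUC2, MUC5AC, SLC16A1, CDKN1A, H1F0 and EPAS1, where bars are group means, error bars are the SD (n = 3) and points are single libraries. H1F0 went from 86.3 to 422.4 CPM with no overlap between groups, while the points of MUC2 and MUC5AC overlap.

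The title also names the hypoxia-inducible factor HIF-2α, a propionate oxidation route and mitochondrial respiration. EPAS1, which encodes HIF-2α, had 9 reads over the 3 controls and 65 with propionate, a ratio of 6.9 (95% interval 3.42 to 15.8, edgeR adjusted p = 0.0014). Without control library 3, which had none of these reads, its fitted log2 fold change was 2.14 against 2.72 (adjusted p = 0.00716, range 0.000123 to 0.00716 over alternatives). It remained a rare transcript, at 0.260 ± 0.230 and 1.75 ± 0.0954 CPM. HIF1A was far more abundant and did not differ beyond the replicate spread, with 47.0 ± 4.12 and 46.1 ± 1.99 CPM (log2 fold change -0.03, SE 0.101, adjusted p = 0.854). Of 53 measured targets of hypoxia-inducible factors, 19 were higher and 3 lower, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.231 with an estimated correlation). Without the members shared with other called lists it missed the threshold (adjusted p = 0.0678). ANGPTL4 led the rises, followed by NDRG1 (1.95-fold), by hexokinase 1 (HK1, 1.91-fold) and by PFKFB4, a regulator of glycolytic flux (3.37-fold). STC2, HILPDA and GBE1 were the members that fell, by 0.88, 0.43 and 0.74 on the log2 scale. A narrower list of 28 genes tied to HIF-2α in intestine, kidney and colon had 7 higher and 3 lower members (camera adjusted p = 0.162). PTGES and SLC2A1 were among the higher members, and TRIB3, YAP1 and SLC11A2 (1.28-fold) were lower. Within 20 genes listed for the HIF subunits and their regulators, 3 were higher, EGLN3, EPAS1 and ARNTL, and 4 were lower, CREBBP, EP300, SIAH1 and SIRT1 (camera adjusted p = 0.408). ARNTL is the clock gene BMAL1 and not the HIF subunit gene ARNT. The list's median (-0.05) and mean (0.05) differed in sign.

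Genes of fatty acid oxidation and of the PPAR receptors, lipid-sensing nuclear receptors, rose as a list: 16 of 40 were higher and 3 lower (16 and 4 adjusted over the list alone, camera adjusted p = 0.0291, and adjusted p = 0.427 with an estimated correlation). Without control library 1 the list missed the threshold (adjusted p = 0.0601, range 0.0106 to 0.427 over alternatives) with its median log2 fold change at 0.16, as with all libraries. Its rises were led by ANGPTL4, by CREB3L3 (8 against 155 reads, ratio 18.5, 95% interval 9.17 to 43.7), by the coactivator PPARGC1A (2.89-fold) and by PPARD (2.08-fold), and its falls were ACOT2, CYP4F3 and ACOT1. ACOT1 and ACOT2 are near-identical copies, so the split of reads between them is uncertain. Of 24 genes of glycolysis and lactate export 7 rose and none fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.455 with an estimated correlation). They included the lactate exporter SLC16A3 (2.87-fold, from 45.6 ± 6.38 to 130.9 ± 11.8 CPM), HK1, PFKFB4 and the enolase ENO2 (1.73-fold). The median of the glycolysis list went from 0.13 to 0.04 on the log2 scale with the GC trend removed in the blocked fit, where it was still called (adjusted p = 0.019, range 0.000352 to 0.455 over alternatives). For the propionate breakdown routes, 8 of 36 genes were higher and 2 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.236), with ACSS2 (1.67-fold), CRAT (1.47-fold), ACADS (1.41-fold) and ABAT (2.12-fold) leading and MMADHC and MMAB lower. The list spans several routes and its leading genes are not specific to propionate oxidation, so these counts do not show a rise of that route.

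Nuclear genes of the respiratory chain showed few and small changes. Of 37 complex I genes 2 were higher and 5 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.441), and of 41 genes of complexes II to V none was higher and 3 were lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.196). The list of complexes II to V was called as lower by the directional fry test (adjusted p = 0.045, but 0.0548 with the replicate block) and by camera with the 3' end GC trend removed in the blocked fit (adjusted p = 0.0339, recentred 0.0239, range 0.0239 to 0.645 over alternatives). NDUFB10 was 1.22-fold higher, NDUFB2 1.23-fold lower and UQCRFS1, the Rieske protein gene of complex III, 1.31-fold lower. Among 33 genes of mitochondrial biogenesis 1 was higher, PPARGC1A, and 6 were lower (camera adjusted p = 0.196), led by GABPB1 (2.78-fold lower), PPRC1, GABPA (2.12-fold lower) and TFAM. The tricarboxylic acid cycle list had 6 higher and 2 lower of 40 (4 and 0 adjusted over the list alone, camera adjusted p = 0.715), with the kinase genes PDK4 and PDK3, PCK1 and IDH3A higher and SDHC lower. The list's median (-0.01) and mean (0.09) differed in sign, and the median was above 0 with upper-quartile factors and with library totals. The 13 protein genes of the mitochondrial genome are not in the deposited tables, so their transcripts could not be examined.

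Propionate is a known inhibitor of histone deacetylases, and genes that respond to such inhibitors were examined. Of 27 measured genes that butyrate or related inhibitors raise, 15 rose and none fell (the same adjusted over the list alone, camera adjusted p = 3.14e-09, and adjusted p = 0.0591 with an estimated correlation). The estimated correlation of this list was 0.00863, below the preset 0.01, so correlated members do not account for the larger p. The linker histone gene H1F0 rose 4.89-fold (SE 0.0991 on the log2 scale, edgeR adjusted p = 2.24e-11), GADD45B 4.73-fold, CEBPA 2.86-fold and the neuronal tubulin gene TUBB3 2.39-fold. CDKN1A, which encodes the cell cycle inhibitor p21, rose 1.66-fold, from 133.2 ± 28.2 to 221.2 ± 25.9 CPM (adjusted p = 0.000111). Of 20 genes that such inhibitors lower, 11 fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 2.64e-07, and adjusted p = 0.207 with an estimated correlation). ASCL2, the mitotic kinase AURKA, CCNB1 and TFAP4 led the falls, and HES1 and ERBB2 were the members that rose. Among 32 genes of the deacetylases and acyltransferases themselves 7 were higher and 9 lower (camera adjusted p = 0.196). This list was called as lower with the GC trend removed in the blocked fit in 4 of 6 versions (adjusted p between 0.0254 and 0.0283, range 0.0254 to 0.652 over alternatives). The acetyltransferase genes KAT6B (2.54-fold), KAT7 (2.39-fold), CREBBP (2.13-fold) and KAT5 (1.97-fold) were lower, while HDAC11 (2.45-fold), SIRT6 (1.68-fold), SIRT7 (1.55-fold) and HDAC3 (1.36-fold) were higher.

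Cell cycle genes fell. Of 36 genes of G2 phase and mitosis 31 were lower and 1, CDC25B, was higher (32 and 1 adjusted over the list alone, camera adjusted p = 2.12e-18). This was the list that stayed called with an estimated correlation (adjusted p = 0.0371), although not in the fit with the replicate block, where the adjusted p with an estimated correlation was 0.289. The G1/S and immediate early lists had the same 0.289 there. Camera with the preset correlation gave the G2/M list an adjusted p of 3.39e-23 in the blocked fit. The block leaves fewer residual degrees of freedom, so this miss does not count against the list. AURKA fell 2.44-fold, from 210.8 ± 18.6 to 86.4 ± 1.20 CPM. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell 2.06-fold, cyclin B1 (CCNB1) 1.82-fold and HMMR 1.84-fold. Of 37 genes of G1/S and DNA replication 20 were lower and 1, the cyclin gene CCNE1, was higher (21 and 1 adjusted over the list alone, camera adjusted p = 0.000106, and adjusted p = 0.312 with an estimated correlation). GINS3 (1.83-fold), RRM2 (1.60-fold), TYMS (1.52-fold) and UHRF1 (1.69-fold) led these falls. The p53 target list had 3 higher and 9 lower of 29 (4 and 9 adjusted over the list alone, camera adjusted p = 0.515). Of 10 measured replication-dependent histone genes, which lack poly(A) tails in dividing cells, 1 passed, HIST1H1D, which was higher, and none passed adjusted over the list alone (camera adjusted p = 0.878).

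**Figure D3:**
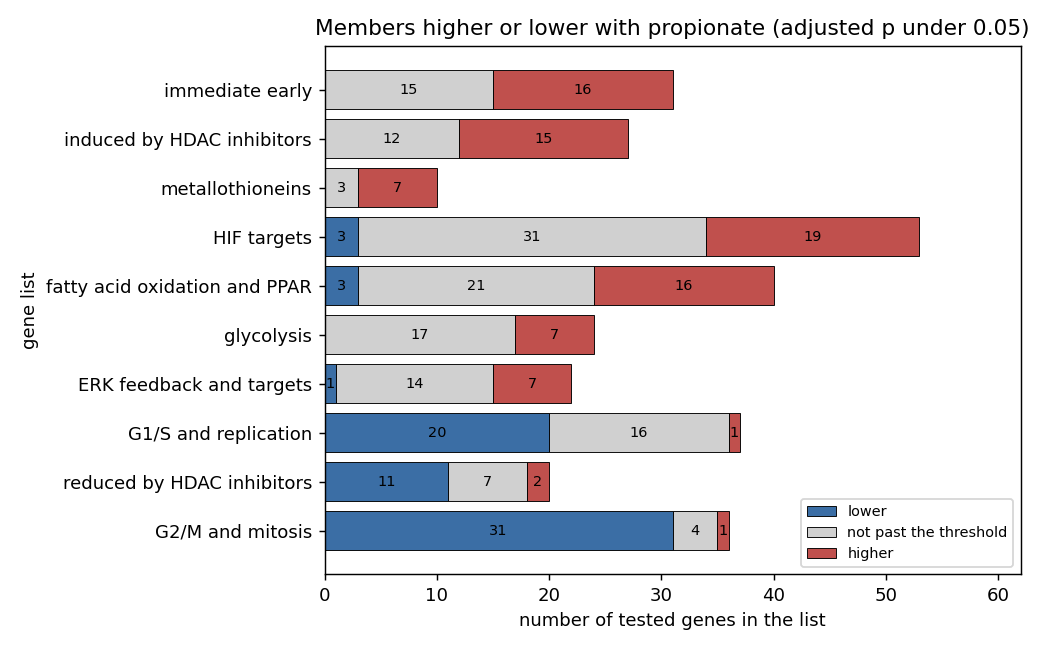
Number of tested genes (x axis) in each of the 10 called gene lists (y axis) that were lower (blue), higher (red) or not past the threshold (grey) with propionate at an edgeR adjusted p under 0.05. In the G2/M list 31 of 36 genes were lower, and in the list of genes raised by histone deacetylase inhibitors 15 of 27 were higher and none lower.

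Immediate early genes, which growth factors and stress switch on within minutes, were higher: 16 of 31 rose and none fell (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.44e-06, and adjusted p = 0.0591 with an estimated correlation). GADD45B, IER3 (2.48-fold, from 181.0 ± 21.6 to 449.2 ± 49.6 CPM), RHOB (2.11-fold) and IER5 (1.87-fold) led. The list's median log2 fold change went from 0.59 to 0.34 with the GC trend removed in the blocked fit, where it was still called (adjusted p = 5.09e-05, range 3.66e-07 to 0.0591 over alternatives). Of 22 read-out and feedback genes of the ERK kinase pathway 7 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00533, and adjusted p = 0.198 with an estimated correlation). The growth factor gene AREG (1.91-fold), ETV5 (2.72-fold) and the phosphatase gene DUSP5 (2.93-fold) were higher and SPRY2 was lower. Metallothioneins, small metal-binding proteins, rose: 7 of 10 were higher and none lower (the same adjusted over the list alone, camera adjusted p = 0.000673, and adjusted p = 0.198 with an estimated correlation). MT2A, the most abundant of those named, went from 1880 ± 98.8 to 2757 ± 217 CPM, and MT1X rose 1.73-fold, MT1H 1.49-fold and MT3 5.29-fold. Their median log2 fold change went from 0.38 to 0.25 with the GC trend removed in the blocked fit, where the list was still called (adjusted p = 0.00333, range 1.82e-05 to 0.198 over alternatives). Metallothionein genes are near-identical copies, so the split of reads among them is uncertain.

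Among 6 measured genes listed for the transport and sensing of short-chain fatty acids, 3 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.252). SLC16A3 and FFAR4 (1.84-fold) rose and OR51E1 fell. FFAR4 encodes a receptor of longer fatty acids, so its rise is not that of a short-chain fatty acid receptor. SLC16A1, the monocarboxylate transporter MCT1, was 1.18-fold higher, at 269.7 ± 23.7 and 317.1 ± 12.9 CPM (log2 fold change 0.23, SE 0.0829, adjusted p = 0.0351), and missed the threshold without propionate library 1 or 2 or control library 2 or 3 (adjusted p between 0.0851 and 0.139), with a log2 fold change of 0.18 to 0.23 in those fits. With the replicate block it was at 0.24 (adjusted p = 0.000473) and with the GC trend removed in that fit between 0.27 and 0.31, and its adjusted p ran from 9.28e-06 to 0.139 over alternatives. Of 24 WNT and intestinal stem cell genes 7 were lower and 1, NKD1, higher (camera adjusted p = 0.0515, and adjusted p = 0.00229 in the fit with the replicate block, with a range of 0.000478 to 0.507 over alternatives). Camera with an estimated correlation gave an adjusted p of 0.507, and of 0.49 with the block. This list passed without control library 1 or 2 or propionate library 2 or 3 (adjusted p between 0.00389 and 0.0427), and its median was above 0 without control library 3. ASCL2, ETS2 (1.51-fold), the ephrin receptor gene EPHB3 (1.95-fold) and RNF43 (1.49-fold) led the falls. Fatty acid synthesis genes had 6 of 24 higher and none lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0629, and adjusted p = 0.0217 with the block, range 0.0217 to 0.372 over alternatives), with the lipogenic factor MLXIPL and AGPAT2 leading.

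Markers of other intestinal and non-epithelial cell types were not called against other genes by camera. Enterocyte markers had 3 higher and 2 lower of 17 (1 and 2 adjusted over the list alone, camera adjusted p = 0.772), with KLF5 higher and CDX2 and CDX1 lower, and its median (0.07) and mean (-0.00) differed in sign. Enteroendocrine markers had 1 lower of 6, INSM1 (camera adjusted p = 0.441), and tuft and Paneth cell markers had 1 higher, TRPM5, and 1 lower, LYZ, of 10 (camera adjusted p = 0.494). Of 6 measured fibroblast markers COL1A1 rose from 0.886 ± 0.237 to 3.68 ± 0.666 CPM and COL6A1 from 30.1 ± 6.35 to 44.1 ± 3.01 CPM (camera adjusted p = 0.265). Of 7 measured leukocyte markers CORO1A rose 5.74-fold, to 37.4 ± 2.63 CPM, CD14 also rose and LYZ fell (camera adjusted p = 0.224, and a directional fry adjusted p = 0.0158, but 0.0741 with the replicate block). CORO1A has a copy, LOC606724, which rose 5.34-fold, so the split of reads between them is uncertain. The median of this list (-0.23) was below 0 while its mean (0.40) and the test's direction were above, and with the stricter filter the median was above 0.

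The remaining lists were not called by camera. Targets of NF-κB had 8 higher and 2 lower of 21 (camera adjusted p = 0.0953), with NFKB2 2.67-fold higher and NFKB1 2.13-fold lower. Interferon-stimulated genes had 9 higher and 3 lower of 23 (0.101 by the same test), led by ISG15 (1.92-fold), and NOTCH genes 8 higher and 3 lower of 22 (0.105), led by the ligand gene JAG2 (2.79-fold). The median log2 fold change of the interferon list went from 0.18 in the blocked fit to -0.0047 with the GC trend removed there (camera adjusted p = 0.16). Antioxidant genes under NRF2 had 3 higher and 6 lower of 31 (0.216), with the heme oxygenase gene HMOX1 4.69-fold higher and KEAP1, whose product restrains NRF2, 2.59-fold lower. Targets of the stress factor ATF4 had 5 higher and 9 lower of 37 (0.252), with CBS higher and SLC7A11, which encodes a cystine transporter, lower. The ATF4 list was called as lower in all 6 versions of the blocked fit with the GC trend removed (adjusted p between 0.00797 and 0.0143, range 0.00797 to 0.76 over alternatives), with its median log2 fold change going from -0.07 to -0.14 in the first. Genes of the unfolded protein response had 5 higher and 4 lower of 29 (0.789), with WFS1 higher and XBP1 lower, and heat shock genes 4 higher and 1 lower of 20 (0.515), with DNAJB1 higher. Cholesterol synthesis genes had 6 higher and 1 lower of 26 (0.515), led by TM7SF2, tight junction genes 5 higher and 4 lower of 27 (0.772), led by TJP3, and polyamine genes 6 higher and 1 lower of 18 (0.495), led by ATP13A2. Targets of retinoic acid, vitamin D and steroids had 6 higher and 2 lower of 20 (0.314), led by PER1 (3.03-fold), and of 76 ribosomal protein genes 1, RPL21, was lower (0.484). Adjusted over the list alone, the counts of these lists were the same except for interferon (9 and 4), NOTCH (9 and 3), tight junction (8 and 4) and ribosomal protein genes (0 and 0).

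Several named genes share bases with another gene on the opposite strand, so their values could hold its reads if counting ignored the strand. These are SLC16A3, HIF1A, SLC2A1, MMAB, IDH3A, SDHC, NDUFB2, GABPA, HDAC11, KAT7, KAT5, ERBB2, TYMS, HMMR, RNF43 and SLC7A11.

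In all, 10 of the 43 tested lists were called by camera with its preset correlation and 1 with an estimated correlation. Regrouping the 6 libraries into the other 9 splits gave between 4 and 14 called lists with the preset correlation, so this count does not set the real grouping apart. The other splits that part all 3 same-number pairs called 7, 4 and 4. The smallest list adjusted p in the other splits lay between 1.35e-07 and 0.0048. Only the G2/M list (2.12e-18) and that of genes raised by histone deacetylase inhibitors (3.14e-09) were below this range by camera in the real grouping. The directional fry test, which asks whether a list's genes moved on balance one way and compares them with no other genes, called 22 lists in the real grouping and 0 in each other split, where between 54 and 375 genes had an unadjusted p under 0.05. In each other split both sides hold treated and control libraries, so the difference between the groups enters the spread. Such a split could hardly call a list, so this 0 was close to fixed in advance and does not set the real grouping apart. Lists called by this fry test and not by camera, also with the replicate block, were those of HIF-2α (adjusted p = 0.00809), mitochondrial biogenesis (0.00611), short-chain fatty acid transport (2.94e-05), NF-κB (0.0135), interferon (0.00499), fatty acid synthesis (0.00573) and NOTCH (0.0166). Those called without the block only were complexes II to V, leukocyte markers, O-glycosylation (0.0162), polyamine (0.045) and retinoic acid, vitamin D and steroid genes (0.036). Called by directional fry with the block only were ATF4 targets (adjusted p = 0.0204, 0.232 without it), NRF2 genes (0.0289 and 0.201), cholesterol synthesis (0.0155 and 0.116) and deacetylases and acyltransferases (0.037 and 0.0668).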

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

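The alternatives that remove a GC trend were chosen after the result was seen; the others were fixed beforehand. Requiring a 1.5-fold change as well left 1345 genes higher and 968 lower. In the fit with the replicate block 2980 genes were higher and 3074 lower. With the GC trend removed in that blocked fit, 2517 genes were higher and 3481 lower in the recentred version, 2561 and 3525 with the trend over 3' ends and 2468 and 3705 with that trend recentred. Of the calls 42%, 42.1% and 40% were thus higher, against 50.3% as reported and 49.2% with the block. The other settings kept both counts within 1.5 times those reported, including leaving out each library (1984 to 2080 higher, 1864 to 1999 lower).

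MUC2 held its call under each scaling, tool, filter, block and thinning alternative without a GC correction. On leaving out libraries its log2 fold change ran from 0.17 without control library 3 to 0.32 without control library 2 and the call was lost in 4 of 6 fits. With the GC trend removed in the blocked fit MUC2 was at 0.035, recentred 0.029, with whole transcripts alone 0.046, recentred 0.038, with 3' ends alone 0.0044, and recentred -0.0090, with an adjusted p of 0.504 or more in each. Only the 3' end version changed sign on recentring. The reference transcript of MUC2, with 393 bases, is shorter than the stretch used for the 3' end measure. Both GC measures of MUC2 thus come from the same sequence, which may not represent its real 3' end. These versions are therefore not separate checks on MUC2. The cause of the lost call with the GC trend removed was not tested.

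MUC5AC changed sign near 0 with size factors of the DESeq2 type (0.0018), upper-quartile factors (0.022), library totals (0.013), DESeq2 (0.0018) and DESeq2 with the replicate block (0.00083), and over fits without 1 library from -0.11 to 0.096. HIF1A changed sign with the GC trend removed in the blocked fit (0.094, recentred 0.087, whole transcripts 0.094, recentred 0.087, 3' ends 0.063, recentred 0.049), and ran from -0.10 to 0.022 over fits without 1 library.

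The number of called lists was 16 with the 3' end GC trend removed in the blocked fit (16 recentred), 1 with an estimated correlation, 22 with the directional fry test and 41 with the mixed one, and between 10 and 13 by camera with its preset correlation in the other fits. In the fit with the replicate block none was called with an estimated correlation. That fit leaves so few residual degrees of freedom that a call was hardly possible, so this does not count against the lists. With the GC trend removed in the blocked fit the median of the goblet list was -0.056, recentred -0.062, whole transcripts -0.062, recentred -0.069, 3' ends -0.049 and recentred -0.062. The histone gene list, which was not called, changed camera's direction in the same fits, with medians, against 0.11 as reported, of 0.016, 0.0086, 0.020, 0.011, -0.023 and -0.037, and its median ran from -0.096 to 0.054 over fits without 1 library. Without control library 2 the fatty acid synthesis list was called (adjusted p = 0.0388), and without control library 3 the NOTCH list was (adjusted p = 0.048). The antioxidant list (adjusted p = 0.0456, recentred 0.0414) and the ribosomal protein list (0.0394, recentred 0.0239) were called as lower with the 3' end GC trend removed in the blocked fit.

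Over the alternatives of the always-named genes and of the largest rises and falls (list members were not run singly), 678 kept direction and call, 13 lost the call, 6 gained one and 16 changed sign. For lists over the camera alternatives 881 kept camera's direction and call, 10 lost the call, 39 gained one and 16 changed direction, which can differ from the sign of the median. The fry tests, which compare a list with no change rather than with other genes, added 12 calls (directional) and 31 (mixed).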

Other observations

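The GC corrections, the GC trend ratio and the tests of symbol families were chosen after the result was seen, although the bounds for the first GC correction were set before its own result. The counts of higher and lower genes were 2343 and 2316, and the highest count in the other splits of the 6 libraries was 0. Both sides of each other split hold treated and control libraries, so the difference between the groups enters the spread. A count near 0 was thus close to fixed in advance there. Of the 10 splits 1 gave as many higher genes and 1 as many lower genes, the real one in each case, and 10 splits are too few for a share under 0.05. As many called lists came from 3 splits, with 10 in the real split and 14 in the highest other. The other splits that part all 3 pairs called 7, 4 and 4 lists.

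GC-rich genes were more often higher and GC-poor genes more often lower with propionate, with a median log2 fold change of 0.18 in the 2634 GC-richest genes and -0.13 in the 2634 GC-poorest. Depth differed little between libraries, with totals from 11603288 to 12746170 reads, which leaves little room for depth as a cause. After thinning every library to the smallest total 97.6% of calls stayed. With so few reads to remove, this share would be high whatever the cause of the calls. A GC bias of the libraries may explain part of the counts. With the trend removed 80% of the blocked fit's 5949 calls stayed (95% interval 78.9 to 81), recentred 80.2%, and with 1 GC measure between 79.6% and 84.2%, where 80% was the bound set beforehand. That interval takes the genes as independent, although all were measured in the same libraries, so it does not cover the uncertainty of the share. The smallest pair trend over GC was 1.82 times the largest between libraries of one group, so a bias shared by all propionate libraries cannot be told apart from a response to propionate, because treatment and library group coincide.

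Of 481 genes with zinc finger symbols, a set picked after its fall was noticed, 43 were higher and 96 lower, with a median log2 fold change of -0.14. Membership went by symbol, so the set also holds antisense RNAs such as ZBTB11-AS1 and pseudogenes such as ZNF137P. Of all 13605 tested genes 2343 were higher and 2316 lower, so the set differed more by having fewer rises than by having more falls. Among families sharing a symbol prefix its main parts were not called: the camera adjusted p was 0.174 for 408 ZNF genes and 0.108 for 38 ZBTB genes, and 0.469 for each with an estimated correlation. Genes of like expression did not fall alike: the medians of 10000 expression-matched random lists ran from -0.08 to 0.13, and 0% were as low. This argues against expression level alone as the cause. Because the set was picked for its fall, the 0% does not measure how unusual that fall is. Their transcripts were GC-poor, with a median of 43.9% against 48.9% for all genes, and with the trend removed in the blocked fit 89% of their median stayed. Relative to all genes the median went from -0.14 to -0.09 (66.2% stayed). Camera on the whole set alone, which was picked for its fall, passed 0.05 in the blocked fit and did not with the GC trend removed, recentred or not. GC bias may therefore contribute to the fall, of which 89% stayed, and cannot be told apart from a response to propionate.

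The rise of the hypoxia-inducible factor target list was weighed against GC bias and a shared rise of core targets. With the GC trend removed 90.8% of its median stayed (87.2% recentred) and the list was still called (adjusted p = 0.00736, range 4e-04 to 0.231 over alternatives), which argues against the GC trend as its whole cause. Of 12 core targets 33.3% were higher, EGLN3, NDRG1, PFKFB4 and SLC2A1, and none lower, between the bounds of 20% and 50% set beforehand. Of all 13605 tested genes 2343 were higher, a share just under the lower bound. With only 12 core targets, their share therefore does not by itself show a response of the pathway. VEGFA (log2 fold change 0.20, adjusted p = 0.127) and CA9 (0.12, adjusted p = 0.821) did not pass. A partial response of this pathway may be present, but whether HIF-2α drives it was not tested.

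Among 60 families of genes with a shared symbol prefix, a test chosen after the data were seen, 1 was called: of 35 RBM genes, which mostly encode RNA-binding proteins, 18 were lower and 2 higher (camera adjusted p = 0.0021, and adjusted p = 0.469 with an estimated correlation).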
